A study of Mus musculus with 6 samples.

How the data were processed

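RNA was measured in liver from 3 WT and 3 PRDX1 Cys52Ser male mice on CDAHFD. Per the labels' protocols, total RNA (5 µg, RIN above 7.0) was extracted with Trizol, selected with oligo(dT) beads, fragmented and made into strand-marked libraries by the dUTP method, with adapters carrying unique molecular identifiers. Libraries were amplified for 8 PCR cycles, had inserts of 300 ± 50 bp and were sequenced as paired 150 bp reads on an Illumina NovaSeq instrument. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, UMI-tools, StringTie 1.3.4d, DESeq2 and edgeR without roles, and the build mm9. The table's coordinates are not mm9: of 28601 genes, 28524 identifiers were found in GENCODE M21 (GRCm38) and 25674 of these (90.0%) had identical coordinates there, so positions are given as GRCm38. Whether counting used the strand is not given in the sources used here, so values of genes that overlap on opposite strands are uncertain.

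The authors deposited 1 table with an estimated count and an FPKM value per gene and sample, per the file headers. The counts are whole numbers, yet for genes with a single transcript and a count of 1000 or more, 89.9% to 92.4% per library lay within 1% of FPKM times length times 1 constant per library. The deposited counts thus follow coverage-based estimates that were rounded up, and whether they stand for reads or fragments is not stated. They needed no further rounding. The FPKM values were scaled by the authors to library size and transcript length. Groups came from the genotype in the titles. Total counts per library were 53318196 to 73900923. Counts also vary with sampling, and the model's dispersion (common biological coefficient of variation 0.358) describes the variation beyond it. No pair of libraries agreed within sampling noise: over genes with at least 50 counts in a pair, chi-square per degree of freedom was 86.9 or more.

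The design fixed before the data were examined named limma on log2(FPKM + 0.5) as the test unless the table also held raw counts. In that case edgeR was to be used. The deposited counts follow coverage-based estimates, so it is open whether they meet this condition. They were taken to meet it, and edgeR 4.0.16 in R 4.3.3 was the main test (filterByExpr with a minimum count of 10, TMM factors trimmed by 30%, robust dispersion and quasi-likelihood fits, genotype as the only term). The limma test on log2(FPKM + 0.5) gave 3290 changed genes, 2919 of them lower, and called Prdx1 lower (limma adjusted p = 0.0132). P-values were adjusted by Benjamini-Hochberg over 18648 tested genes, at a threshold of 0.05. Levels are TMM-scaled CPM (counts relative to the effective library size) with SD over 3 mice, and the standard error of a log2 fold change was its size divided by the square root of the F statistic. Genes with 0 counts throughout a group were given as bounds against 3 counts over the group, which cover counting error in that group only. Gene lists were written before the data were examined and tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry. A list needed 5 tested genes, which held for 38 of 39 lists; the exocrine pancreas list had 4. GO terms with 15 to 300 tested genes came from the deposited table.

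Named genes followed a rule fixed beforehand: Prdx1; the 12 largest increases and 12 largest decreases among changed genes with non-overlapping groups, leaving out gene-model symbols; the 3 smallest p-values in each list; a fixed set of 24 liver, fibrosis, inflammation, lipid and redox genes; and 3 members of each of the 5 leading GO terms per direction. Genes named beyond it are stated as such. Some genes that the rule takes are not reported here by name, though they stay in the counts.

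On counts simulated from the real means, library sizes and dispersions (18648 genes), the test recovered 31 of 48 genes raised 4-fold and 23 of 44 lowered 4-fold, but only 10 of 50 raised 2-fold and 10 of 46 lowered 2-fold. It called 8 of 17846 unchanged genes, which made 9.8% of 82 calls false. Far fewer genes were changed in this simulation than the 928 called in the real data. With Benjamini-Hochberg adjustment a smaller share of changed genes makes each call harder, so these recoveries need not hold for the real data. When the matrix list was raised 2-fold, that list alone was called. Genes were drawn independently of each other there, so this does not show how the list test behaves with correlated genes. The real matrix list had an estimated correlation of 0.597.

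Alternatives were other scaling factors (RLE, upper quartile, library totals), other filters, non-robust fits, DESeq2 1.42.0, a block on the replicate number, leaving out each library, and limma on FPKM with pseudocounts of 0.1, 0.5 and 1, other filters, rescaling, quantile normalization, array weights and moderation without both trend and robust estimation. DESeq2, the other count scalings, the mean CPM filter and non-robust fits were added after the data were seen. Limma with a pseudocount of 0.5 was the design's own test for a table without raw counts. Its use as an alternative to edgeR was decided after the data were seen. Transcript length and GC content came from the longest GENCODE M21 transcript of each gene.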

Results

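Liver RNA was sequenced from 6 male mice fed a choline-deficient, L-amino acid-defined, high-fat diet (CDAHFD), which produces steatohepatitis and fibrosis in mice. Of these, 3 mice were wild type (WT) and 3 carried the Cys52Ser substitution in peroxiredoxin 1 (PRDX1), an enzyme that reduces hydrogen peroxide through this cysteine. The diet began at 8 weeks of age and lasted 8 weeks according to the sample titles and the series design. The treatment field of the same samples instead counts upward by 1 week per sample, from 8 to 10 weeks in WT and from 11 to 13 weeks in Cys52Ser. If that field were literally true, genotype and time on the diet could not be separated. The single comparison asks how the substitution changes the liver transcriptome during diet-induced steatohepatitis.

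Total counts per library lay between 53318196 (WT replicate 2) and 73900923 (Cys52Ser replicate 1). Albumin alone took 3.6%, 5.3% and 5.55% of the counts in WT replicates 1, 2 and 3, and 8.08%, 8.26% and 8.49% in the Cys52Ser replicates. The TMM scaling factors also parted the groups, at 1.21, 1.14 and 1.05 in WT and 0.885, 0.963 and 0.814 in Cys52Ser. WT libraries had mean correlations of 0.968 to 0.969 with their own group, and Cys52Ser libraries 0.932 to 0.954. Cys52Ser replicate 3 had the fewest genes detected, 21516 against 22926 to 23865 in WT.

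**Figure D1:**
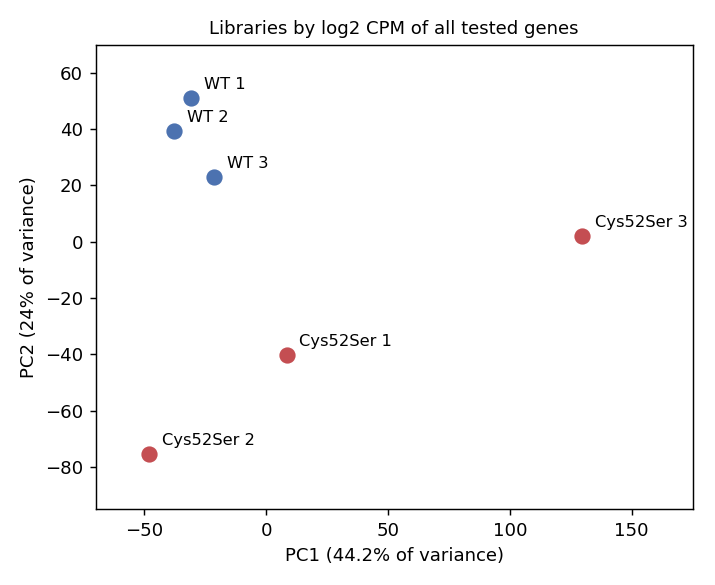
Each point is 1 library placed by the first 2 principal components of log2 CPM over all tested genes, with WT in blue and Cys52Ser in red. The first component (44.2% of the variance) sets Cys52Ser replicate 3 apart at 129.6, and the second (24%) places the 3 WT libraries at 23.1 to 51 and the Cys52Ser libraries at 2.1 or below.

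Prdx1 (ENSMUSG00000028691, GRCm38 chromosome 4, 116685544 to 116700822) was measured at 920 ± 57.2 CPM in WT and 780 ± 105 CPM in Cys52Ser (SD, n = 3 each). The log2 fold change was -0.24 with a 95% confidence interval from -0.60 to 0.12, and the edgeR adjusted p was 0.421. All 3 Cys52Ser libraries lay below all 3 WT libraries, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 samples allow. On the deposited FPKM scale the level was 301.4 ± 5.78 in WT and 199.9 ± 17.2 in Cys52Ser (SD, n = 3 each), a log2 difference of -0.60. The call depended on the normalization. Prdx1 was called lower with library totals alone (log2 fold change -0.59, edgeR adjusted p = 0.0188) and in limma on quantile-normalized FPKM (-0.65, adjusted p = 0.021), but not on TMM-rescaled FPKM (-0.23, adjusted p = 0.399). A substitution of 1 residue is not visible in gene-level counts, so these values do not check the genotype labels.

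Among genes of peroxiredoxins, thioredoxins and their partners, Glrx, which encodes glutaredoxin, rose 2.12-fold from 33.3 ± 2.73 to 70.4 ± 2.75 CPM (SD, n = 3 each; edgeR adjusted p = 0.0114). Srxn1, encoding the sulfiredoxin that repairs overoxidized peroxiredoxins, was 1.9-fold lower, at 192 ± 11.3 CPM in WT and 101 ± 16.0 CPM in Cys52Ser (SD, n = 3 each; edgeR adjusted p = 0.0234). These were the only calls among the 21 tested peroxiredoxins, thioredoxins and partners, over all genes and also adjusted over the list alone. Sesn3 had a log2 fold change of -0.30 (adjusted p = 0.136) and Txnrd1 one of -0.14 (adjusted p = 0.533). The list as a whole was not shifted (camera adjusted p = 0.591), and its median log2 fold change of 0.03 became -0.32 with library totals alone. Of 34 NRF2 targets and glutathione enzymes, Gsta3 rose 2.20-fold, and Srxn1 and Cbr3 fell, Cbr3 by 1.20 on the log2 scale. Adjusted over the list alone, 2 were higher and 3 lower, and the list was not shifted (camera adjusted p = 0.144), though it was shifted lower in 6 of 24 alternatives, including those without WT replicate 2 (adjusted p = 0.0184) or Cys52Ser replicate 3 (adjusted p = 0.036). Nqo1, a standard NRF2 target, had a log2 fold change of -0.09 (adjusted p = 0.926), and of -0.71 without Cys52Ser replicate 2 (adjusted p = 0.0791).

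Across the transcriptome, 928 of 18648 tested genes changed (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), 469 higher and 459 lower in Cys52Ser. At 2-fold or more, 203 were higher and 256 lower. In all 928 the groups did not overlap, and this held for 5531 of all tested genes, 29.7% against the 10% that chance gives for 3 against 3. The count fell to 409 without WT replicate 1, 57 without WT replicate 2 and 790 without WT replicate 3. It was 31 without Cys52Ser replicate 1, 504 without Cys52Ser replicate 2 and 28 without Cys52Ser replicate 3. Each such fit leaves 2 mice in 1 group, so lost power and dependence on single libraries cannot be told apart. All 928 genes kept their direction in these fits. As their groups do not overlap, leaving out 1 library could hardly reverse a direction, so this is no separate support. Scaling by library totals alone moved the median log2 fold change of all genes to -0.35 and gave 293 higher and 2724 lower genes, so that 9.7% of the calls were higher instead of 50.5%.

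Leaving out gene-model symbols, the largest increase belonged to Cd163, the haemoglobin scavenger receptor of resident macrophages (chromosome 6, 124304656 to 124330527), which rose 13.7-fold from 2.91 ± 2.20 to 39.6 ± 5.16 CPM (SD, n = 3 each; edgeR adjusted p = 0.0237). It was followed by Srcap at 11.9-fold, the acyl-CoA thioesterase Acot3 at 9.13-fold, Tnnc1 at 7.81-fold, Gpx6 at 6.57-fold, Lingo4 at 6.37-fold, Kcnj16 at 6.23-fold and Myom3 at 6.23-fold. Cxcl13, Fgf1, Trim80 and the ferritin receptor gene Scara5 rose 5.80-fold, 5.63-fold, 5.61-fold and 5.59-fold. The Srcap value is uncertain because other annotated genes lie within it on the same strand, and Acot3 also overlaps another gene model and has close paralogs. The calls of Tnnc1, Myom3 and Trim80 were lost in 6 of 14 alternatives each, that of Kcnj16 in 7 of 14 and that of Lingo4 in 4 of 14. Those of Gpx6 and Cxcl13 were lost in 8 and 6 of 23. Those of Acot3, Cd163 and Scara5 were lost in 4, 3 and 5 of 24, that of Srcap in 1 of 15 and that of Fgf1 in 0 of 25. The WT group held only 41, 53 and 65 counts of Tnnc1, Trim80 and Lingo4. Some of these increases were larger with 1 library left out. The log2 fold change of Cd163 was 3.77 and became 4.52 without WT replicate 3. That of Acot3 went from 3.19 to 3.94 without WT replicate 2 and that of Tnnc1 from 2.97 to 3.72 without WT replicate 1. Lingo4 also begins just after the end of another gene on the same strand, so its value is uncertain. Fgf1 and Lingo4 each overlap a gene on the opposite strand. The one across from Lingo4, the antisense gene model Gm43401, had 0 counts in every WT library and 0.676 ± 0.173 CPM in Cys52Ser (SD, n = 3), at least 44.4-fold higher against a floor of 3 counts over the group; it lies outside the rule for named genes and was chosen after its values were seen.

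Among the largest decreases, Armc3, Nlrp9b, Klhl38, Tmem52 and Katnal2 had 0 counts in every Cys52Ser library and WT means of 0.418, 0.399, 0.289, 0.28 and 0.276 CPM. They were at least 25.2-fold, 21.8-fold, 16.0-fold, 15.7-fold and 16.0-fold lower against a floor of 3 counts over the group. These bounds take the WT level as measured, from 87, 75, 55, 54 and 55 counts. The calls of these genes were lost in 9, 9, 10, 9 and 10 of 14 alternatives. Asz1 was 52.4-fold lower, from 3.35 ± 1.57 to 0.0599 ± 0.0612 CPM (SD, n = 3 each; edgeR adjusted p = 0.0262), a size that rests on 11 counts in the Cys52Ser group. Gabrp was 21.2-fold lower, Scube3 18.1-fold, the microfibril gene Fbn2 15.1-fold, Nrip2 12.7-fold and Foxj1, a regulator of motile cilia, 11.3-fold. Foxj1 fell from 8.82 ± 5.10 to 0.780 ± 0.147 CPM (SD, n = 3 each; edgeR adjusted p = 0.0174). The processed pseudogene Cbx3-ps8 was 11.4-fold lower, a value that is uncertain because such copies share reads with their parent gene. The log2 fold change of Asz1 went from -5.71 to -6.79 without Cys52Ser replicate 1 (adjusted p = 0.0756). That of Gabrp went from -4.41 to -3.80 and -5.14 without Cys52Ser replicates 1 and 2 (adjusted p = 0.0708 and 0.0588), and that of Scube3 from -4.18 to -3.56 without WT replicate 1. Nrip2, Scube3 and Klhl38 overlap genes on the opposite strand.

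**Figure D2:**
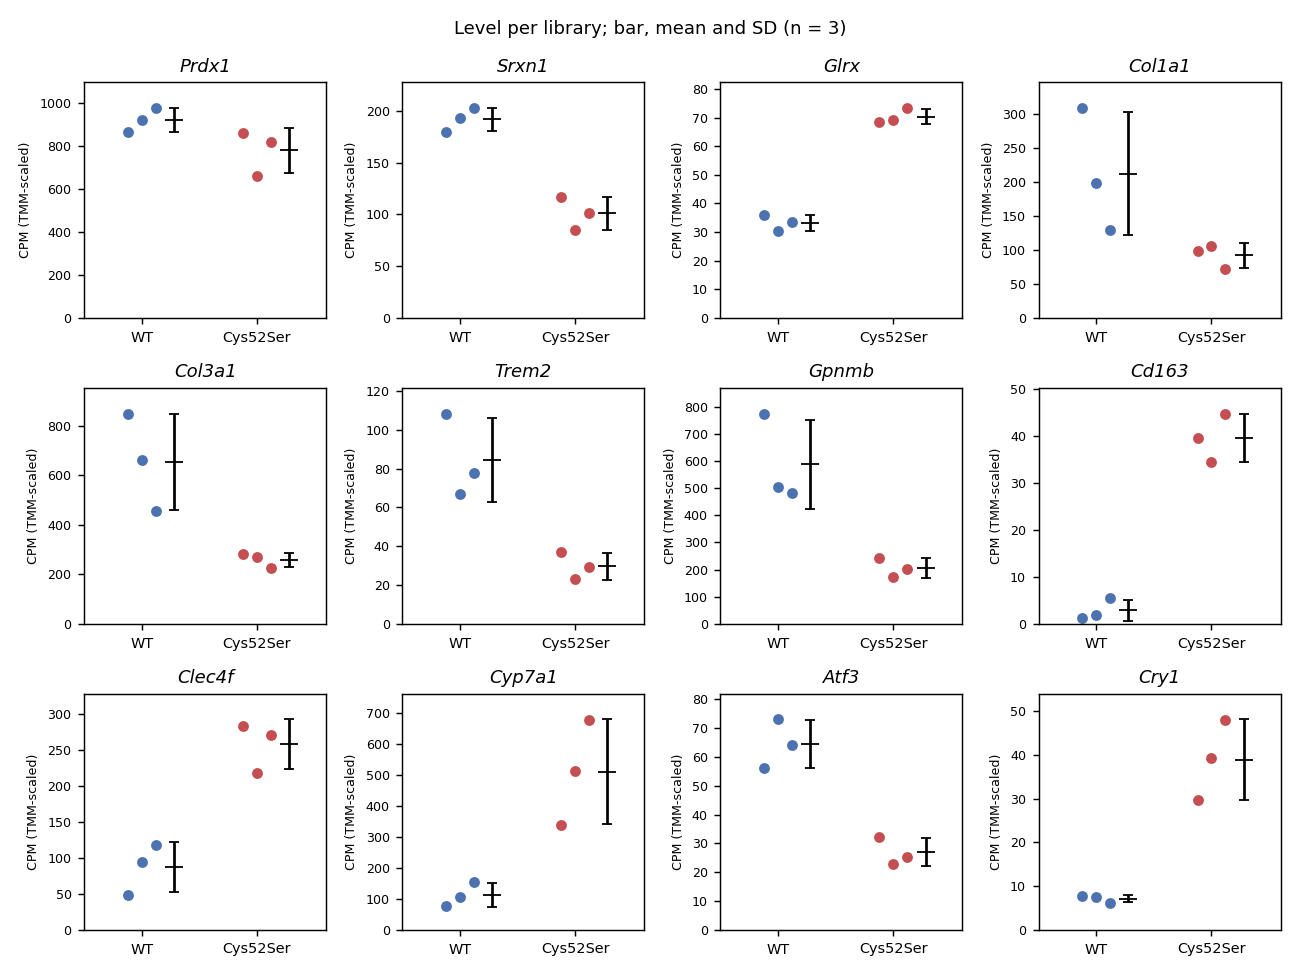
Points give TMM-scaled CPM of 12 genes in each library on linear axes from 0, WT in blue and Cys52Ser in red, and the bar beside each group gives its mean and SD (n = 3). Prdx1 averages 920 and 780 CPM, Cd163 rises from 2.91 to 39.6 CPM and Gpnmb falls from 587 to 206 CPM.

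Lists of fibrosis genes were shifted lower in Cys52Ser. Of 35 tested collagens and matrix genes, 12 fell and 1 rose, and 26 fell and 1 rose adjusted over the list alone; the median log2 fold change was -1.06. Col6a3 (chromosome 1, 90765923 to 90843971) was 3.57-fold lower, at 143 ± 48.3 CPM in WT and 39.9 ± 3.29 CPM in Cys52Ser (SD, n = 3 each; edgeR adjusted p = 0.0189). Lum was 3.21-fold, Col5a2 2.30-fold and Col3a1 2.53-fold lower. Col1a1 did not pass, at 213 ± 91.1 against 92.4 ± 18.4 CPM (SD, n = 3 each; edgeR adjusted p = 0.0823), though it passed in 12 of 25 alternatives. Timp1 did not pass either, at a log2 fold change of -0.30 (adjusted p = 0.8), which was -1.11 without Cys52Ser replicate 2 (adjusted p = 0.12). The member that rose was Fn1, fibronectin, which hepatocytes secrete in large amounts, at 1.74-fold. Of 20 stellate cell and myofibroblast markers, 5 fell and 9 fell adjusted over the list alone, among them Ngfr (2.90-fold lower), Tgfb2 (4.16-fold lower) and the quiescent stellate cell marker Cygb (2.84-fold lower). Acta2, the usual marker of activated myofibroblasts, was 22.96 ± 5.86 CPM in WT and 38.9 ± 44.7 CPM in Cys52Ser (SD, n = 3 each; edgeR adjusted p = 0.674). Its higher Cys52Ser mean came from replicate 2 alone, at 90.4 CPM against 16.5 and 9.86 CPM in replicates 1 and 3, and without replicate 2 the log2 fold change was -0.80 (adjusted p = 0.172). Both lists were shifted lower (camera adjusted p = 5.53e-20 and 4.6e-05); adjusted p = 0.292 for each with an estimated correlation. The stellate call was lost in 8 of 24 alternatives, all limma on FPKM (adjusted p from 0.0975 to 0.282), and the list's mean log2 level in Cys52Ser replicate 2 (4.82) lay within the WT range of 4.5 to 4.93.

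Macrophage genes divided by type. Of 25 markers of monocyte-derived and lipid-associated macrophages, 7 fell, 17 fell adjusted over the list alone, and all 25 had negative log2 fold changes. Gpnmb (chromosome 6, 49036546 to 49070929) fell from 587 ± 163 to 206 ± 35.9 CPM, 2.85-fold lower (SD, n = 3 each; edgeR adjusted p = 0.0234). Trem2, a lipid receptor of these cells, was 2.84-fold lower and Cd9 2.35-fold lower. Spp1, osteopontin, was 779 ± 332 CPM in WT and 197 ± 120 CPM in Cys52Ser (SD, n = 3 each) and did not pass (edgeR adjusted p = 0.0692). It passed in 13 of 25 alternatives, among them the fit without Cys52Ser replicate 2 (log2 fold change -2.60 instead of -1.98, adjusted p = 0.0396). The list was shifted lower (camera adjusted p = 4.65e-16; adjusted p = 0.292 with an estimated correlation). Of 14 Kupffer cell markers, the resident macrophages of the liver, 3 rose and none fell, over all genes and adjusted over the list alone, and 10 had positive and 4 negative log2 fold changes. The 4 were the complement genes C1qa, C1qb and C1qc and Slc11a1, named after their values were seen, at -0.17, -0.40, -0.24 and -0.42, with every Cys52Ser library below every WT library and adjusted p from 0.134 to 0.443. Those that rose were Cd163, Clec4f, which rose 2.96-fold from 87.1 ± 35.1 to 257 ± 34.6 CPM (SD, n = 3 each; edgeR adjusted p = 0.0425), and Folr2, which rose 2.30-fold. This list was shifted higher (camera adjusted p = 0.00121; adjusted p = 0.359 with an estimated correlation), a call lost in 3 of 24 alternatives, all limma on FPKM (adjusted p from 0.0686 to 0.259).

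Other cell types also moved apart. Of 18 dendritic cell and antigen presentation markers, 5 fell and 8 fell adjusted over the list alone. H2-Aa was 1.97-fold, Cd74 1.99-fold and H2-Eb1 1.93-fold lower, all genes of MHC class II presentation. Of 20 cholangiocyte and ductular reaction markers, Pkhd1 (3.57-fold lower) and Cldn7 (5.64-fold lower) fell; adjusted over the list alone, 5 were lower and 1 higher. Epcam had a log2 fold change of -1.93 (adjusted p = 0.0632). Both lists were shifted lower (camera adjusted p = 1.47e-06 and 4.6e-05; adjusted p = 0.292 and 0.329 with an estimated correlation). The cholangiocyte call was lost in 9 of 24 alternatives, all limma on FPKM (adjusted p from 0.0594 to 0.747), and the list's mean log2 level in Cys52Ser replicate 2 (3.43) lay above that in WT replicate 3 (3.24). Of 22 sinusoidal endothelial markers, 5 rose, including Kdr (1.57-fold), Dnase1l3 (1.62-fold) and Cdh5 (1.76-fold), and adjusted over the list alone 7 were higher and 1 lower. That list was shifted higher (camera adjusted p = 0.000472; adjusted p = 0.292 with an estimated correlation), although its median log2 fold change of 0.29 turned to -0.07 with library totals alone.

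Lymphocyte and neutrophil lists were not shifted. Among 24 T cell and NK cell markers, Il7r fell by 1.66 on the log2 scale and was the only call, also adjusted over the list alone (camera adjusted p = 0.942). None of 19 B cell and plasma cell markers passed over all genes, with 1 higher adjusted over the list alone (camera adjusted p = 0.823), and none of 17 neutrophil markers passed either way (camera adjusted p = 0.417, and 0.0286 without Cys52Ser replicate 1). None of 7 tested red blood cell genes passed, while the list was shifted higher (camera adjusted p = 0.0437; adjusted p = 0.321 with an estimated correlation); that call was lost in 7 of 24 alternatives, including those without WT replicate 1, Cys52Ser replicate 1 or Cys52Ser replicate 3 (adjusted p = 0.157, 0.0745 and 0.0639). None of 7 adipocyte genes passed, and their median of -0.49 and mean of 0.06 differed in sign (camera adjusted p = 0.646). Only 4 exocrine pancreas genes were tested, too few for the list test, and none passed. Clps stood at 203.4 CPM in Cys52Ser replicate 2, the library that also stood apart for Acta2, against 23.6 and 0 CPM in replicates 1 and 3 and 9.76 to 28.9 CPM in WT, while Cela1 and Ctrl in that library were 12.6 and 0.203 CPM, within the range of the other 5. Of 42 chemokines and inflammatory cytokines, 4 fell and Cxcl13 rose; adjusted over the list alone, 6 were lower and 1 higher. Cxcl16 was 1.95-fold lower and Ccl2, the monocyte chemoattractant, 2.19-fold lower, at 12.01 ± 1.82 against 5.47 ± 1.19 CPM (SD, n = 3 each; edgeR adjusted p = 0.0338). Tnf, Il1b and Cxcl10 did not pass (adjusted p = 0.517, 0.843 and 0.529). The list was shifted lower (camera adjusted p = 0.0186; adjusted p = 0.4 with an estimated correlation), a call lost in 11 of 24 alternatives: without WT replicate 3 or Cys52Ser replicate 2 (adjusted p = 0.176 and 0.0764), with library totals alone (0.0614) and in 8 fits of limma on FPKM (0.109 to 0.556). None of 40 interferon response genes passed, while the list was shifted higher with a median log2 fold change of 0.32 (camera adjusted p = 0.00335; adjusted p = 0.659 with an estimated correlation), a median that was -0.01 with library totals alone. The interferon call was lost in 4 of 24 alternatives, including those without WT replicate 1, WT replicate 2 or Cys52Ser replicate 1 (adjusted p = 0.0739, 0.314 and 0.0591).

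Lists of hepatocyte genes were shifted higher in Cys52Ser, in the libraries that also gave a larger share of counts to albumin. Of 29 hepatocyte identity genes, 5 rose, 24 rose adjusted over the list alone, and all 29 had positive log2 fold changes. The urea cycle gene Cps1 rose 2.64-fold from 1493 ± 400 to 3943 ± 595 CPM (SD, n = 3 each; edgeR adjusted p = 0.0302), Hpd rose 2.32-fold and the transcription factor gene Hnf4a 1.9-fold. Albumin itself (Alb) averaged 2.17-fold the WT level and did not pass (adjusted p = 0.0574). Of 18 periportal genes 5 rose, including Hal (2.56-fold), Asl (2.90-fold) and Sfxn1 (1.77-fold), and adjusted over the list alone 12 were higher and 1 lower. Of 18 pericentral genes Cyp2c37 rose, also adjusted over the list alone, by 3.47-fold, and Cyp2e1 did not pass (adjusted p = 0.108). Of 28 cytochrome P450 and xenobiotic genes 8 rose and 20 rose adjusted over the list alone, among them Cyp2f2 (2.57-fold), Sult1a1 (2.22-fold) and Por (2.58-fold). Of 32 acute phase genes 5 rose, including Il6ra (4.42-fold), Serpina3m (3.62-fold) and Saa4 (4.09-fold), and adjusted over the list alone 13 were higher and 1 lower; Saa1 did not pass (adjusted p = 0.173). These 5 lists were shifted higher, with camera adjusted p from 5.69e-17 for hepatocyte identity to 4.44e-07 for pericentral genes; adjusted p = 0.3 for pericentral genes and 0.292 for the other lists with an estimated correlation.

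Lists of bile acid, choline and fatty acid metabolism genes were also shifted higher, though most of their members did not pass the test. Cyp7a1 (chromosome 4, 6265612 to 6275633), the rate-limiting enzyme of classical bile acid synthesis, rose 4.5-fold from 113 ± 38.8 to 509.6 ± 169 CPM (SD, n = 3 each; edgeR adjusted p = 0.0243). In total 6 of 23 bile acid genes rose, 11 adjusted over the list alone, with Akr1d1 at 2.63-fold and Slc27a5 at 2.28-fold. Of 33 choline, phospholipid and one-carbon genes 8 rose, including Ahcy (2.91-fold), Sardh (2.25-fold) and Shmt1 (1.78-fold), and adjusted over the list alone 14 were higher and 1 lower. Of 38 PPAR-alpha targets and fatty acid oxidation genes 9 rose and 1 fell, and adjusted over the list alone 19 were higher and 3 lower. Ppara itself rose 2.78-fold and Acot4 3.40-fold, while Crot, a peroxisomal carnitine acyltransferase, was 1.94-fold lower. Cpt1a, the entry step of mitochondrial oxidation, had a log2 fold change of 0.46 (adjusted p = 0.234). The 3 lists were shifted higher (camera adjusted p = 2.04e-08, 1.33e-07 and 8.84e-10); adjusted p = 0.292 for each with an estimated correlation.

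Lipid synthesis and export genes were partly higher. Of 24 fatty acid synthesis genes 3 rose, including Fads1 (1.89-fold) and Srebf1 (2.13-fold), 10 adjusted over the list alone, while Fasn and Scd1 had adjusted p of 0.746 and 0.911; the log2 fold change of Fasn went from 0.38 to 1.18 without WT replicate 1 (adjusted p = 0.129). Of 27 cholesterol synthesis genes 2 rose, 7 adjusted over the list alone. Of 20 VLDL and lipoprotein genes Mttp (1.55-fold) and Lcat (1.73-fold) rose, 5 adjusted over the list alone. Of 21 gluconeogenesis and glucose handling genes 1 rose, 5 adjusted over the list alone. The 4 lists were shifted higher (camera adjusted p = 6.05e-07, 1.03e-06, 8.12e-06 and 3.23e-05; adjusted p = 0.292, 0.377, 0.292 and 0.321 with an estimated correlation). Of 27 lipid droplet and fatty acid uptake genes 5 rose, including Plin5 (2.73-fold) and Fitm2 (1.72-fold), and the fatty acid translocase Cd36 was 1.67-fold lower; adjusted over the list alone, 5 were higher and 3 lower. That list was not shifted (camera adjusted p = 0.0607), with a median of 0.27 that was -0.08 with library totals alone, but was shifted higher in 11 of 24 alternatives: without WT replicate 2, Cys52Ser replicate 1 or Cys52Ser replicate 2 (adjusted p = 0.0105, 0.0249 and 0.0407), without a count filter (0.0165) and in 7 fits of limma on FPKM (0.0127 to 0.0464), where its median was negative. Cidec had a log2 fold change of -0.74 (adjusted p = 0.201).

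Respiratory chain genes leaned upward with few calls. None of 36 nuclear-encoded genes passed, over all genes or adjusted over the list alone, although all 36 had positive log2 fold changes with a median of 0.35, which was -0.05 on FPKM divided by column totals. Of 13 mitochondrially encoded genes mt-Nd4l rose 2.20-fold, and 8 rose adjusted over the list alone. Both lists were shifted higher (camera adjusted p = 8.23e-09 and 9.28e-08; adjusted p = 0.377 and 0.292 with an estimated correlation), the mitochondrially encoded call being lost in 1 of 24 alternatives, quantile-normalized FPKM (0.344). None of 23 male-biased genes passed and Acot3 was the only call of 20 female-biased genes, 5 adjusted over the list alone. Both sex-biased lists were shifted higher (camera adjusted p = 8.19e-05 and 0.000196; adjusted p = 0.391 and 0.292 with an estimated correlation).

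Lists of stress genes were shifted lower. Of 32 ER stress and integrated stress response genes 6 fell and 15 fell adjusted over the list alone, among them the ER chaperone cofactor gene Sdf2l1 (1.81-fold lower), Manf (1.85-fold lower) and Atf3. Atf3, also an immediate early gene, fell from 64.5 ± 8.37 to 26.9 ± 4.90 CPM, 2.40-fold lower (SD, n = 3 each; edgeR adjusted p = 0.0169). Of 22 immediate early genes Atf3, Klf6 and Junb fell, 5 adjusted over the list alone. Of 26 p53 targets and senescence genes Phlda3 was 2.17-fold lower, and 5 fell adjusted over the list alone. These lists were shifted lower (camera adjusted p = 1.02e-08, 0.0222 and 0.0116; adjusted p = 0.292, 0.3 and 0.31 with an estimated correlation). The immediate early call was lost in 11 of 24 alternatives: without WT replicate 1 or Cys52Ser replicate 1 (adjusted p = 0.0648 and 0.174) and in 9 fits of limma on FPKM (0.0963 to 0.471). The p53 call was lost in 1, limma with a mean FPKM of at least 5 (0.0974). Of 36 proliferation genes Rrm2 rose 2.42-fold and was the only call, also adjusted over the list alone. The proliferation list was shifted higher (camera adjusted p = 0.0123; adjusted p = 0.661 with an estimated correlation), with a median of 0.27 that was -0.05 with library totals alone. It was not shifted in 7 of 24 alternatives, including those without WT replicate 1, WT replicate 3 or Cys52Ser replicate 2 (adjusted p = 0.0911, 0.0632 and 0.927), and the median was -0.11 without the last of these.

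Clock genes changed in both directions. Of 22 circadian genes 9 rose and 2 fell, and adjusted over the list alone 11 were higher and 3 lower. Cry1, a repressor of the core clock, rose 5.43-fold from 7.16 ± 0.907 to 38.9 ± 9.17 CPM (SD, n = 3 each; edgeR adjusted p = 0.0107). Per2, another repressor of the clock, rose 2.46-fold. The 2 that fell, named after their values were seen, were Nr1d1 (3.48-fold lower) and Bhlhe41 (2.39-fold lower). The list was shifted higher (camera adjusted p = 6.16e-08; adjusted p = 0.292 with an estimated correlation). The hour of collection is not given in the sources used here.

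**Figure D3:**
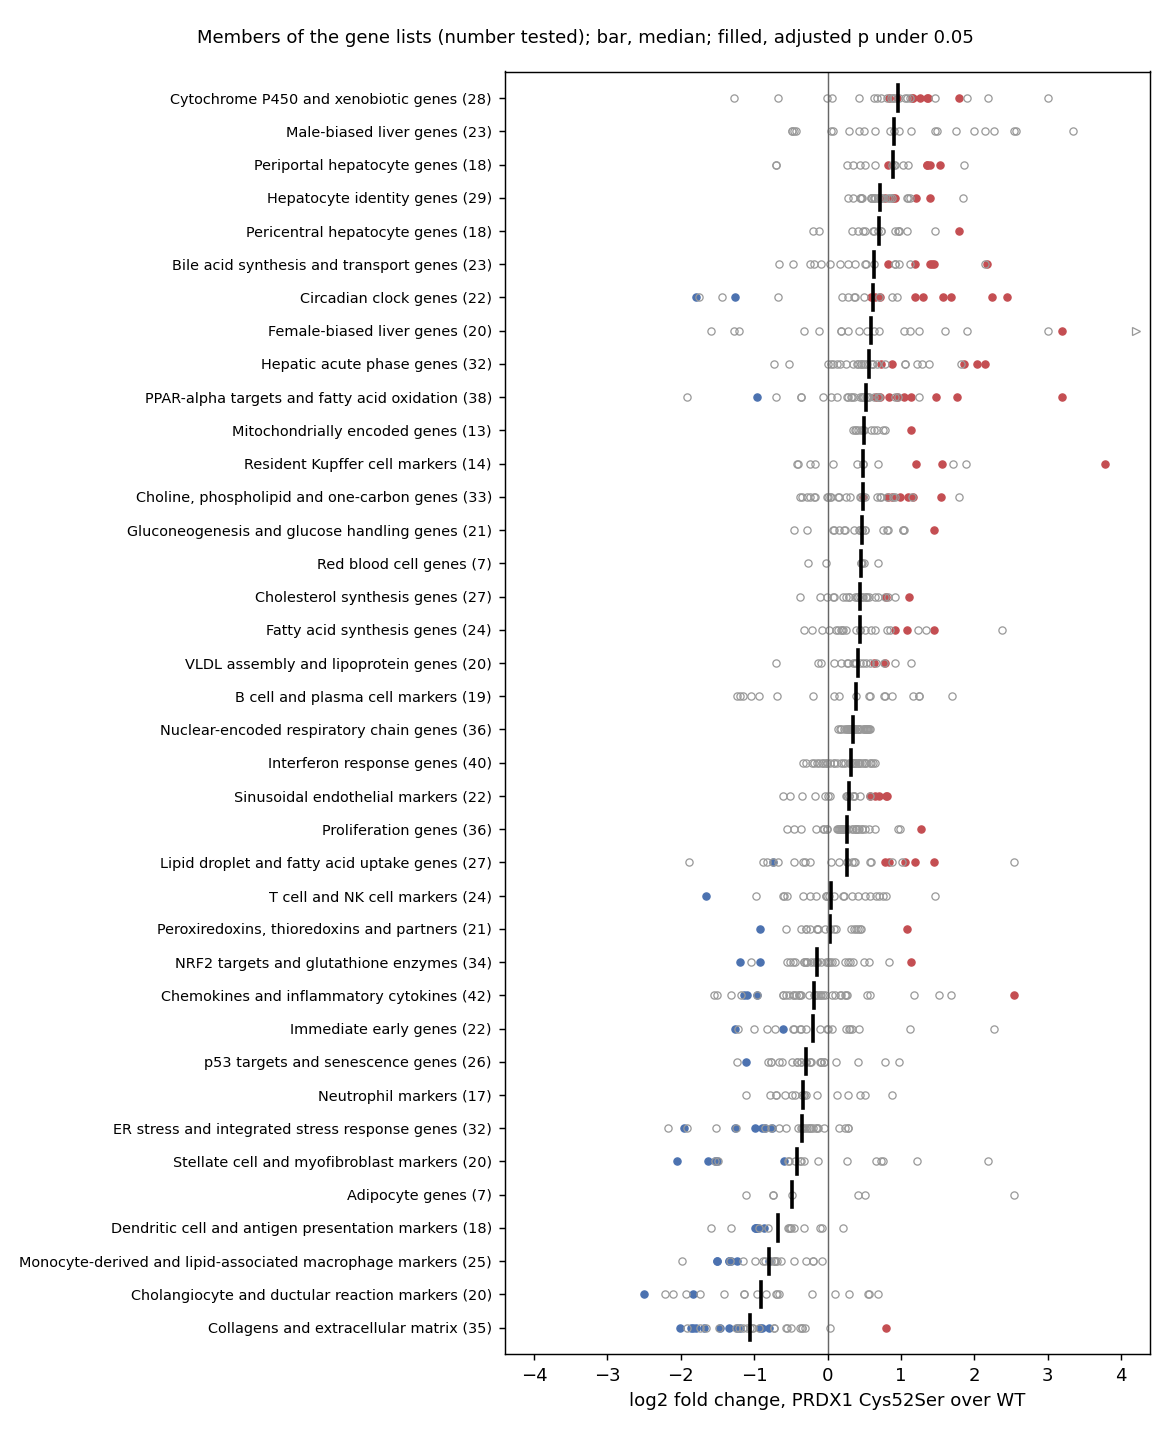
Each line is a gene list with the number of tested members, each point is the log2 fold change of 1 member in Cys52Ser over WT, filled where the edgeR adjusted p is under 0.05 (red higher, blue lower), and the black bar is the list's median; an arrowhead marks a value beyond the axis. Medians run from -1.06 for collagens and matrix genes to 0.96 for cytochrome P450 and xenobiotic genes.

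In the list test with the preset correlation, 31 of 38 lists were shifted, 22 higher and 9 lower. With an estimated correlation 0 were, the smallest adjusted p being 0.292. At the preset correlation, divisions of the libraries that mix the genotypes, but keep part of any genotype difference, shifted up to 29 lists. The directional fry test, which asks only whether a list's genes move one way on balance, passed 0 lists, and fry's mixed test passed 29. Of 2473 Gene Ontology terms given in the deposited table, 209 were shifted (camera, preset correlation), 125 higher and 84 lower. The 5 smallest p-values among higher terms belonged to acyl-CoA metabolic process (Ces1d, Acnat2, Acot4), peroxisome (Acnat2, Acot4, Acsl1), respirasome (mt-Nd4l, mt-Cytb, Ndufs7), acute-phase response (Saa4, Cd163, Fn1) and sterol esterase activity (Ces1d, Ces1e, Ces2a). Ces1d, a liver carboxylesterase, rose 5.5-fold and Acnat2 4.30-fold, both with close paralogs that can share reads; mt-Cytb and Ndufs7 did not pass (adjusted p = 0.0667 and 0.0678). Among lower terms they belonged to collagen fibril organization (Cyp1b1, Lum, Col5a2), extracellular matrix (Spon2, Fgf1, Adamts9), extracellular matrix structural constituent conferring tensile strength (Col6a3, Col4a4, Col5a2), collagen binding (Ddr1, Ctsk, Lum) and extracellular matrix organization (Adamts9, Adamts12, Itga8). Spon2 was 3.59-fold lower and the collagen-degrading protease gene Ctsk 3.81-fold lower, while Fgf1 rose. With an estimated correlation the unadjusted p of these 10 terms ran from 0.0288 for acyl-CoA metabolic process to 0.236 for respirasome.

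Of 111 named genes past the threshold, 57 remained past it without WT replicate 1, 18 without WT replicate 2, 81 without WT replicate 3, 13 without Cys52Ser replicate 1, 69 without Cys52Ser replicate 2 and 13 without Cys52Ser replicate 3. None changed sign in any of these fits, which non-overlapping groups made nearly certain beforehand. The 8 that remained past it in all 6 of them included Ces1d, Cry1, Fgf1, Glrx, Il6ra, Per2 and Spon2.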

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

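The library-total, RLE and upper-quartile scalings, the mean CPM filter, non-robust fits and DESeq2 were chosen after the data were seen. Limma with a pseudocount of 0.5 was fixed beforehand as the test for a table without raw counts. The 928 changed genes kept their direction in every alternative that tested them. For fits without 1 library this was nearly fixed beforehand, since the groups overlap in none of these genes. Past the threshold, 917 remained with RLE factors, 912 with upper-quartile factors, 918 with DESeq2, 731 with library totals alone and 563 with a replicate block. Far fewer remained without some libraries: 348 without WT replicate 1, 50 without WT replicate 2, 590 without WT replicate 3, 27 without Cys52Ser replicate 1, 421 without Cys52Ser replicate 2 and 27 without Cys52Ser replicate 3.

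Changed genes numbered 3017 with library totals alone (293 higher, 2724 lower) and 2766 with DESeq2 (1498 higher, 1268 lower). With a mean CPM of at least 5, 710 were higher. Without a count filter, 322 GO terms were shifted. Deviations from the group means correlated at -0.04, 0.14 and 0.02 between libraries of the same replicate number. Such deviations cancel within each small group by construction, so these values cannot tell whether the numbers pair the mice. A block on the replicate number gave 303 lower genes. Leaving out 1 library at a time gave 28 to 790 changed genes (21 to 378 higher, 7 to 412 lower) and 138 to 293 GO terms. Each such fit has 2 mice in 1 group. Gene lists numbered 0 with an estimated correlation and 24 to 32 in the other alternatives. DESeq2 gives no list or GO values.

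On deposited FPKM, limma gave 3290 changed genes, 2919 lower and 122 GO terms with a pseudocount of 0.5. The same 3 counts were 3285, 2916 and 121 with a pseudocount of 0.1, 3265, 2896 and 120 with 1, 2978, 2658 and 122 without both trend and robust estimation, 5369, 4684 and 115 with array weights, and 2980, 2635 and 121 with a replicate block. Column totals gave 3868 (307 higher, 3561 lower) and 118 GO terms. A mean FPKM of at least 5 gave 2207 genes, 1882 lower. No filter gave 174 higher, 1091 lower and 773 GO terms. TMM rescaling returned the balance of directions, with 593 higher and 449 lower.

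Prdx1 was called lower in the alternatives that follow. Its log2 fold change was -0.5944 with library totals alone, -0.5945 in limma with a pseudocount of 0.5, without filter, with a mean FPKM of at least 5, without both trend and robust estimation and with a replicate block, -0.5955 and -0.5933 with pseudocounts of 0.1 and 1, -0.6503 after quantile normalization, -0.6562 with column totals and -0.5855 with array weights. Its adjusted p ran from 0.00538 to 0.688 over all alternatives. Apart from quantile normalization, the alternatives that called Prdx1 lower used library or column totals. They also moved the median log2 fold change of all genes to between -0.352 and -0.221, against -0.003 in the main fit. They thus share 1 kind of scaling and are not separate support for a lower Prdx1. After TMM rescaling of FPKM its log2 fold change was -0.23 (adjusted p = 0.399), while quantile normalization, which also balanced the directions (568 higher, 664 lower), kept the call. The cause of the call after quantile normalization was not tested.

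The list of peroxiredoxins, thioredoxins and partners was called lower in limma without a filter (median -0.307, adjusted p = 0.0357), and the proliferation list turned lower without Cys52Ser replicate 2 (median -0.1116, adjusted p = 0.927), its median running from -0.1116 to 0.4122 as each library was left out. For both, and for the counts above, the cause was not tested. Of the other list values, 817 kept their side of the threshold, 61 lost the call and 18 gained it. For named genes these were 3143, 551 and 291. The kept values include genes that changed sign without a call, such as Acta2 in 10 of 25 alternatives. They also include lists whose median changed sign, such as endothelial markers, from 0.289 to -0.065 with library totals alone.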

Other observations

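The tests of a single scaling factor, of the share of hepatocyte RNA and of clock phase were chosen after the results were seen, and the genes of the first paragraphs below were singled out after their values were seen.

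Some GO terms of motile cilia were shifted lower in Cys52Ser with the preset correlation, although few of their genes passed the edgeR test. The terms axoneme assembly (16 tested genes, median log2 fold change -0.71, camera adjusted p = 0.0033), motile cilium assembly (17 genes, -0.56, adjusted p = 0.00338) and cilium movement (24 genes, -1.12, adjusted p = 0.00688) had 1, 1 and 0 genes that fell; their unadjusted p was 0.0619, 0.076 and 0.0729 with an estimated correlation. Foxj1, which encodes a transcription factor of motile cilia, was the gene with the smallest p in the first 2 of these terms.

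Among genes outside the fixed lists, Fkbp5 rose 5.42-fold from 48.9 ± 15.9 to 264.6 ± 37.8 CPM (SD, n = 3 each; edgeR adjusted p = 0.013). Zbtb16 rose 5.37-fold from 5.17 ± 1.56 to 27.7 ± 6.58 CPM (SD, n = 3 each; edgeR adjusted p = 0.0168). The imprinted RNA H19 stood at 177 CPM in WT replicate 2 and at 5.73 to 19.8 CPM in the other 5 libraries (edgeR adjusted p = 0.482).

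The hepatocyte list was higher while the matrix list was lower, their medians running from 0.29 to 0.81 and from -1.42 to -0.84 over 24 alternatives. Over all genes, 5 of 29 hepatocyte genes passed as higher and 12 of 35 matrix genes as lower. Both list calls were lost with an estimated correlation (camera adjusted p = 0.292 for each). A single scaling factor per library adds the same log2 amount to every gene and cancels from a difference between lists, but the changes of these lists, fixed before the data were examined, differed by 1.84 on the log2 scale (SE 0.471). A higher share of hepatocyte RNA alone would lower every other cell type alike, but endothelial markers differed from matrix genes by 1.27 (SE 0.305), and Kupffer markers from lipid-associated macrophage markers by 1.84 (SE 0.477); the endothelial list differed less clearly from stellate markers (0.783, SE 0.355) and cholangiocyte markers (1.33, SE 0.517), where the groups overlapped. After each library's trends on transcript length and GC content were removed, the hepatocyte and matrix lists still differed by 1.79 (SE 0.387), and 876 of the 928 genes were still changed. Fewer matrix-producing cells and recruited macrophages per liver, lower expression in each of these cells, different time on the diet and genotype remain open and may act together.

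Clock genes changed in both directions, which a shift of clock phase between the groups may explain. Log2 changes of 16 clock genes were fitted by a cosine of their textbook peak hours, with an R squared of 0.606 and a permutation p of 0.0018 (10000 permutations of the peak hours across genes, which are not independent replicates). The fitted amplitude was 1.87, with the largest increase at a peak hour of 16.9. Dbp, an output gene of the clock, had a log2 fold change of -1.44 (edgeR adjusted p = 0.0706). Whether such a shift would come from the hour of collection, feeding or genotype was not tested, and rhythmic metabolic genes could move with it.

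The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. For changed genes 1 division, the real one, gave as many as 928, and the highest other gave 1. For gene lists the real division gave 31, reached by 1 division, and the highest other 29. Divisions that mix the genotypes gave 8 to 29 lists, with at most 1 changed gene. Each such division still holds unequal numbers of the genotypes on its sides, so part of any genotype difference remains in it. It also places that difference within the groups, which can lower the number of changed genes. These divisions thus cannot tell how many lists would be called without a genotype difference. With an estimated correlation, 0 lists were called in the real division. For GO terms 4 of the 10 gave at least the real 209. The highest, 576, set WT replicates 1 and 2 and Cys52Ser replicate 2 against the rest, which points to a structure of the samples; its nature was not tested.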
